A study of Homo sapiens with 6 samples.

How the data were processed

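Total RNA from the human induced pluripotent stem cell line 201B7 was hybridised to 6 Affymetrix arrays as biotin-labelled cDNA. The arrays covered cells given SOX-L or vehicle, sampled on days 3, 4 and 5, with 1 array for each treatment and day. All 6 arrays were assigned to a treatment and a day from the characteristics in the labels. The labels' treatment text states RNA extraction on day 5, while titles and characteristics give days 3, 4 and 5; the days of the titles and characteristics were used.

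The deposited values are log2 expression values per probe set, which the authors made with RMA, per the submitters' processing notes. Those notes name Affymetrix Expression Console 1.3.1 and Transcriptome Analysis Console 2.0. RMA corrects background, quantile-normalises the arrays and summarises probes into 1 value per probe set, so each array was placed on the same distribution before deposit and a change shared by most genes would not be visible. The median over probe sets lay between 4.08 and 4.12 on every array. The table holds no detection calls and no scan dates, so batches could not be looked for, and the depth of an array has no counterpart of a read count. The precision is limited by the number of arrays.

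The value table holds 53617 probe sets. The platform annotation used here lists 25713 of them, of which 23871 have 1 gene symbol and 1842 have several, while 27904 are not listed and stay unnamed. Symbols were updated through the gene identifier for 22569 of the probe sets with 1 symbol, against a RefSeq gene table of assembly GRCh38.p14, and 90 were renamed. Where a gene had more than 1 probe set (632 genes), the one with the highest mean over the 6 arrays stood for the gene. This left 22395 genes for testing. As a stand-in for detection calls, the background level was set at the 95th percentile of the means of 358 olfactory receptor genes, log2 4.30, and 14155 genes had a mean above it. No gene was removed for low signal in the main tests. For genes with arrays below this level, a bound on the difference was computed with each array counted at no less than the level, a step added after the results were seen. No coordinates are given, since the build behind the array annotation was not given in the sources used here.

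Differences between SOX-L and vehicle were tested with limma 3.58.1 in R 4.3.3 by fitting treatment with day as a factor, followed by empirical Bayes moderation with an intensity trend and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. That fit has 2 residual degrees of freedom and a prior of 4.87. Its error is the day-to-day variation of the treatment difference, because a single day has no replicate. The labels do not say whether the arrays came from separate cultures or from 1 experiment, so the p-values measure only the spread between these arrays, which may be technical. A shared change per day was tested with day as a number and treatment as a factor, with 3 residual degrees of freedom and a prior of 5.05. That fit does not pair the arrays of a day. A deviation shared by both arrays of a day is counted as if seen independently, which can make its p-values too small. A treatment-by-day term tested whether the difference changed from day to day, with 2 residual degrees of freedom and a prior of 5.48. Single days were described without a test, by counts of genes at 2-fold or more and by the percentile of each list's median among 10000 random lists of the same size matched on mean expression. Adjusted p-values for genes are from these limma fits.

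The 30 fixed gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists, and again with camera at an estimated correlation and with fry. Of 493 list members, 447 were matched to a tested gene. For each list, the number of members past the threshold is given both over all genes and adjusted over the list alone. The lists, the main tests and the rule for named genes were set before the data were examined, as were the alternatives other than those given below as chosen after the result was seen. By that rule, 23 developmental genes were always named, of which 21 were measured; PDGFRA and TNNT2 were not analysed here. The rule also named the 12 largest increases and the 12 largest decreases among genes past the threshold, above background and changed the same way on all 3 days, and the 5 largest differences each way on each day. It further took the 6 largest each way for the day trend and for the treatment-by-day term, and up to 2 members each way of every list. Not all of the list members it took are given below. Genes whose probe sets carry several symbols, Y-linked genes and XIST were not named. Genes named outside the rule are given as chosen after their values were seen.

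The fits were tested on simulated data with the real genes, 50 of them changed at each size. Gene means were fitted means, the spread was limma's moderated variance, and changed genes were drawn from those above background. The changes followed the fitted model exactly, so the shares below hold for data that suit it. For treatment, 29 of 50 genes changed by log2 0.5 were recovered and all 50 at each of 1, 2 and 3, with 20 false calls, 10.1% of the calls. The day trend recovered all 50 at every size, with 14 false calls (6.5% of the calls). The treatment-by-day term recovered 7 of 50 at 0.5, 44 at 1 and all 50 at 2 and 3, with 2 false calls (1.3%). In the list test, a list of 20 genes shifted by 0.5 had an adjusted p of 1.18e-50 at the preset correlation and 0.0759 with an estimated correlation, and 0 of 20 unshifted lists passed with camera either way. Noise was drawn independently for each gene, so the list test could not show how camera behaves when members are correlated. In the real lists the estimated correlation reached 0.918, for cholesterol synthesis.

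Alternatives covered filters on intensity, moderation without trend or with robust settings, renewed quantile normalisation, centring of each array, the mean of a gene's probe sets, other day terms, other thresholds, other list tests, and leaving out each day. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Dixon's test for outlying samples was not applied, as no group had 4 arrays.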

Results

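SOX-L is a pyrrole-imidazole polyamide, a synthetic small molecule built to bind a chosen DNA sequence, and the series title describes it as a DNA-binding inhibitor of SOX2 used to steer pluripotent cells towards cardiac mesoderm. The cells were 201B7, an established human induced pluripotent stem cell line kept undifferentiated in mTeSR1 medium on Matrigel. From 2 days after plating they received 2 µM SOX-L or vehicle in a serum-poor medium, and RNA was profiled on days 3, 4 and 5. The data were 6 arrays, 1 for each treatment and day, with RMA log2 values for 22395 named genes. Across genes, pairs of arrays correlated at r = 0.981 to 0.993. Genes are not independent replicates, so these correlations carry no test. Errors of mean differences below are SDs over the 3 daily differences (n = 3 days), and single days have no replicate.

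The first question was which genes differed between SOX-L and vehicle cells over the 3 days. Genes of the primitive streak and early mesoderm were among those furthest above vehicle. EPAS1, a hypoxia-inducible transcription factor, was at least 10.2-fold higher, with a mean log2 difference of 3.42 ± 0.70 (limma adjusted p = 0.0053). CER1, a secreted antagonist of NODAL, BMP and WNT ligands, was at least 7.17-fold higher (3.29 ± 0.88, adjusted p = 0.0106), and EOMES, a T-box factor of the primitive streak, was at least 4.90-fold higher (2.95 ± 0.69, adjusted p = 0.00745). HAND1, a transcription factor of cardiac and extraembryonic mesoderm, was 7.02-fold higher at 2.81 ± 0.40 (adjusted p = 0.00162). NODAL, the ligand that induces mesendoderm, was higher by 2.65 ± 1.03 (adjusted p = 0.0266). Vehicle signal lay below the background level on all 3 arrays for CER1 and EOMES, on 2 for NODAL and on 1 for EPAS1, and folds written as at least count each array at no less than that level.

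DACT1, a regulator of WNT signalling, was at least 6.16-fold higher (2.89 ± 0.38, adjusted p = 0.00162), with 1 vehicle array below background. HAS2, a hyaluronan synthase, was 5.91-fold higher and WLS, which carries WNT proteins to the cell surface, was higher by 2.46 ± 0.33, both with the same adjusted p as DACT1. SEMA3D, a secreted guidance cue, rose by 2.52 (adjusted p = 0.00597) and the endothelin receptor EDNRB by 2.50 (adjusted p = 0.0122) while ARID5B was at least 3.50-fold higher (adjusted p = 0.0411). The pseudogene BCRP3 was higher by 2.63 (adjusted p = 0.0168), but its probes could also read near-identical copies. Vehicle signal was below background on all 3 arrays for ARID5B and on 2 for BCRP3.

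Decreases were smaller. GRPR, the receptor for gastrin-releasing peptide, was 3.76-fold higher in vehicle than in SOX-L cells (mean log2 difference -1.91 ± 0.59, adjusted p = 0.0165). CLGN, a chaperone of the endoplasmic reticulum, differed by -1.86 ± 0.45 (adjusted p = 0.0108). The forebrain factors HESX1, SIX3 and FEZF1 fell by 1.33, 1.29 and 1.19 on the log2 scale, with adjusted p = 0.0124, 0.00597 and 0.0188, while OTX1, also a forebrain factor, rose by 1.34 (adjusted p = 0.0417). The antisense RNA FEZF1-AS1 fell by 1.52 (adjusted p = 0.00664), and MIR124-1HG, the host gene of a neuronal microRNA, fell by 1.25 (adjusted p = 0.0154). The other named decreases were LUZP2 (-1.47), ALDH1L2, a mitochondrial folate enzyme (-1.49), CLIC6 (-1.32), MEIOC (-1.09, with its SOX-L mean below background) and the pseudogene PGAM1P5 (-1.07), whose probes could read its parent gene. Their adjusted p-values lay between 0.00597 and 0.0254.

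In all, 203 of 22395 genes passed an adjusted p of 0.05, 112 higher and 91 lower with SOX-L, and 71 of them differed by 2-fold or more in the mean (57 higher, 14 lower). All 203 differed the same way on all 3 days, which is no separate evidence, because the fit takes its error from the day-to-day variation of the difference. An unadjusted p under 0.05 was found for 3714 genes, against 1120 by chance. The count for SOX-L vs vehicle, mean of days 3 to 5, was 1025 without day 3, 16 without day 4 and 103 without day 5. It was 1 without the day term, 54 without the intensity trend, 566 with day as a number, and 352 or 392 with the filters on low signal. EPAS1, EOMES, DACT1, HAND1, HAS2, SEMA3D, WLS, LUZP2 and FEZF1-AS1 stayed under 0.05 whichever day was left out, while without day 4 the calls were lost for CER1, NODAL, EDNRB, ARID5B, BCRP3, GRPR, CLGN and the other named decreases. Without day 5 those of ARID5B, ALDH1L2 and CLIC6 were lost as well.

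The target of the compound and the other fixed developmental genes were then read one by one. SOX2 had a mean log2 level of 11.32 in vehicle and 11.04 in SOX-L cells, a difference of -0.28 ± 0.11 that missed the threshold (adjusted p = 0.0892) and passed it without day 3 or with day as a number. The pluripotency factors POU5F1 and NANOG differed by 0.06 ± 0.20 and -0.36 ± 0.24 (adjusted p = 0.793 and 0.235). Beside EOMES and HAND1, the second-heart-field factor ISL1 rose 3.70-fold (1.89 ± 0.79, adjusted p = 0.0341), a call lost without day 4, without the trend and with robust moderation. The streak ligand WNT3 was 2.77-fold higher by its brightest probe set (1.47 ± 0.30, adjusted p = 0.0108), while its other 2 probe sets differed by -0.26 and -0.003. With the mean of its probe sets the WNT3 difference was 0.40 (adjusted p = 0.142), and its call was also lost without day 4.

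MIXL1, a homeobox factor of the streak, had differences of 1.23, 4.75 and 4.00 on the 3 days, a mean of 3.33 ± 1.85 that missed the threshold (adjusted p = 0.0613), with vehicle signal below background on 2 of 3 arrays. It passed when day 3 was left out, with day as a number and with the filters on low signal. The mesoderm genes TBXT, KDR, GATA6 and GATA4 had mean differences of 0.91, 1.19, 1.56 and 0.75 (adjusted p = 0.101, 0.119, 0.116 and 0.206), and all 4 passed when day 3 was left out. The WNT effector LEF1 differed by 1.00 ± 0.45 (adjusted p = 0.0544) and passed under several alternatives, among them centring each array. The cardiac genes MESP1, TBX5 and NKX2-5 differed by 0.16, 0.21 and 0.22 (adjusted p = 0.539, 0.454 and 0.584). The endoderm genes SOX17 and FOXA2 differed by 0.40 and 0.06, the neural genes PAX6 and SOX1 by 0.32 and 0.07, and BMP4 by -0.01, with adjusted p-values from 0.258 to 0.981. The means of GATA4, TBX5, NKX2-5 and SOX1 lay below the background level in both treatments.

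**Figure D1:**
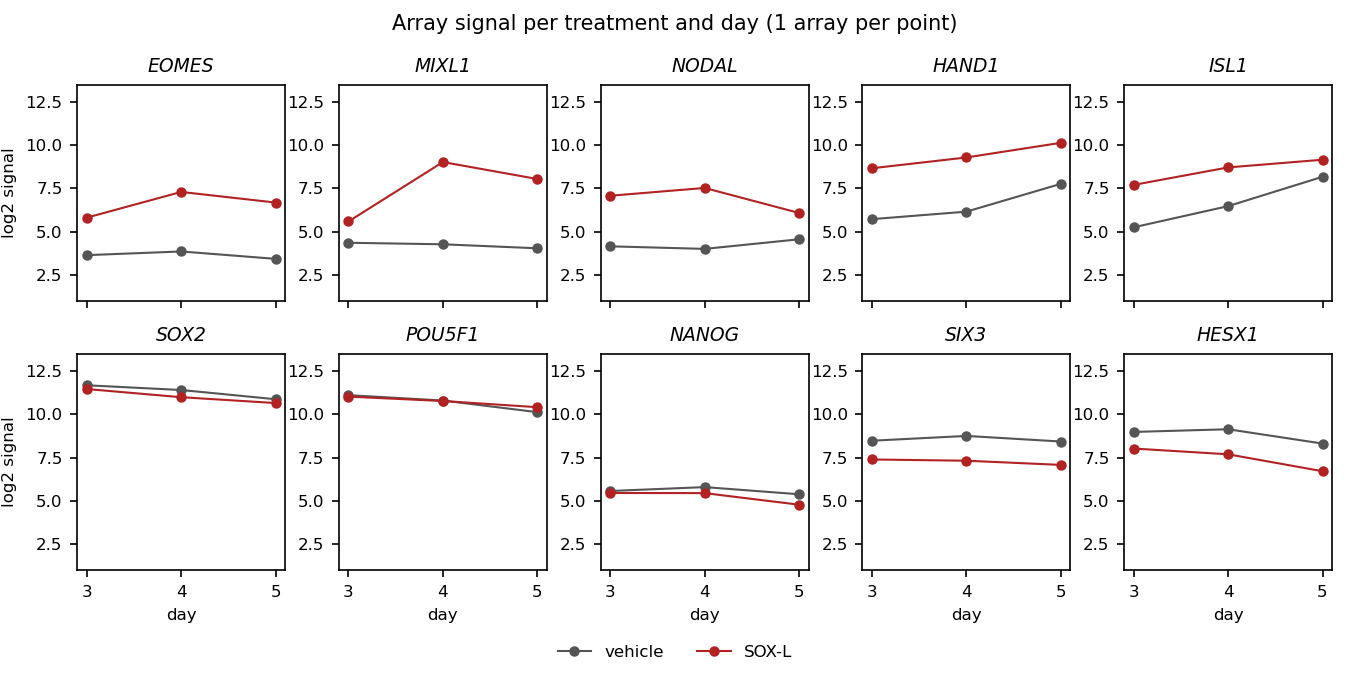
Log2 signal (y axis) of 10 genes on days 3, 4 and 5 (x axis) in vehicle (grey) and SOX-L (red) cells; each point is 1 array, and both rows share 1 scale. EOMES, HAND1, ISL1 and NODAL lie above vehicle on all 3 days, SIX3 and HESX1 lie below it, and SOX2 differs by a mean of -0.28.

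Among the 30 gene lists, primitive streak and mesendoderm genes showed the smallest p with camera at the preset correlation. All 20 measured members were higher in SOX-L cells, with a median log2 difference of 0.76 (camera adjusted p = 7.69e-15; adjusted p = 0.523 with an estimated correlation). Over all genes 5 members passed, CER1, EOMES, NODAL, WNT3 and the WNT-responsive factor SP5 (1.37), and 15 passed adjusted over the list alone. The calls of CER1, NODAL, WNT3 and SP5 were lost without day 4. WNT targets were higher in 11 of 11 members with a median of 0.97 (camera adjusted p = 1.98e-11; adjusted p = 0.523 with an estimated correlation). Theirs was the smallest unadjusted p of the lists in camera with an estimated correlation (0.0176) and in fry (0.00412). Passing members were 5 over all genes and 9 adjusted over the list alone. Beside SP5, the 5 were the feedback inhibitors RNF43 (1.25 ± 0.31), NKD1 (1.02 ± 0.19) and AXIN2 (0.82 ± 0.25) and the receptor TNFRSF19 (0.93 ± 0.20), named after their values were seen. The stem cell receptor LGR5 had a difference of 2.07 ± 1.45 (adjusted p = 0.1), or at least 1.75 with 2 vehicle arrays raised to the background level.

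Genes of cholesterol synthesis were higher in 14 of 14 members, with a median of 0.60 (camera adjusted p = 3.77e-10; adjusted p = 0.523 with an estimated correlation). Over all genes 0 passed in limma, where the smallest adjusted p was 0.0682, while 14 had an unadjusted p under 0.05 and 14 passed adjusted over the list alone. HMGCS1, the enzyme that makes the precursor of mevalonate, differed by 1.20 ± 0.96, and MSMO1 by 0.77 ± 0.76. The list of ATF4 targets and the unfolded protein response was lower, with 14 of 16 members below vehicle and a median of -0.39 (camera adjusted p = 8.04e-06; adjusted p = 0.524 with an estimated correlation). Over all genes 1 member passed, the lipoprotein receptor VLDLR (-0.93 ± 0.08), named after its value was seen, and adjusted over the list alone 8 were lower and 1, the chaperone HSPA5 (0.28), was higher. TRIB3 and DDIT3, stress genes downstream of ATF4, differed by -1.60 ± 1.33 and -1.47 ± 1.17 (adjusted p = 0.138 and 0.134), DDIT3 with all 3 SOX-L arrays below background. With arrays raised to the background level the DDIT3 difference was -0.88.

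Markers of neural crest were higher in 11 of 12 members (median 0.99, camera adjusted p = 0.000144; adjusted p = 0.523 with an estimated correlation). The 11 include SOX10 at 0.003 and SOX9 at 0.13, while the receptor NGFR differed by -0.54 ± 0.45 (limma adjusted p = 0.18). EDNRB passed over all genes, and 7 members were higher and 1 lower adjusted over the list alone. SNAI2, a repressor of epithelial genes, differed by 2.34 ± 2.48, with 5.06 on day 5. Lateral and cardiac mesoderm genes had a median of 0.15, with 17 of 22 members above vehicle (camera adjusted p = 0.00136; adjusted p = 0.523 with an estimated correlation). HAND1 and ISL1 passed over all genes and 5 members adjusted over the list alone. Trophoblast and amnion markers had a median of 0.19 (camera adjusted p = 0.00073; adjusted p = 0.523 with an estimated correlation), with 0 members past the threshold over all genes in limma, 6 at an unadjusted p under 0.05 and 3 adjusted over the list alone. Their largest differences were GABRP at 3.19 ± 1.79 (adjusted p = 0.0617) and VTCN1 at 2.02 ± 1.63 (adjusted p = 0.131), the latter at least 1.45 since all 3 vehicle arrays were below background.

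The p53 target list was lower, with 19 of 22 members below vehicle and a median of -0.20 (camera adjusted p = 0.00073; adjusted p = 0.523 with an estimated correlation). Over all genes 0 passed in limma and 11 had an unadjusted p under 0.05, and adjusted over the list alone 4 were lower and 2 higher. Of these genes GDF15, a stress-induced secreted factor, differed by -0.98 ± 0.57 (adjusted p = 0.0818). TP53INP1 and TP53I3 went the other way, by 0.45 ± 0.21 and 0.38 ± 0.20 (limma adjusted p = 0.102 and 0.131). The pluripotency list was lower with a median of -0.16 (camera adjusted p = 0.0202; adjusted p = 0.523 with an estimated correlation). Its median differences on days 3, 4 and 5 were -0.14, -0.22 and -0.004, and on day 5 11 of 22 members were above vehicle. Of its 22 members 0 passed over all genes in limma and 10 had an unadjusted p under 0.05, and adjusted over the list alone 5 were lower and 2 higher. PRDM14, a repressor of differentiation, differed by -0.48 ± 0.20 and CRIPTO, the NODAL co-receptor, by -0.49 ± 0.28, while GDF3, below background on 2 vehicle arrays, differed by 1.16 ± 0.84 (adjusted p = 0.0655, 0.153 and 0.117).

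With an estimated correlation, camera also missed a simulated list with a true shift and independent members (adjusted p = 0.0759). WNT targets were lost as well, at an estimated correlation of -0.015. A loss in that setting thus does not show that correlated members made the call. Further lists passed with camera and were lost with an estimated correlation. WNT ligands and antagonists had a median of 0.27 (camera adjusted p = 0.0114; adjusted p = 0.524 with an estimated correlation), with WNT3 and SFRP2 (0.46, named after its value was seen) higher and the antagonist SFRP1 (-0.52 ± 0.14) lower over all genes. Adjusted over the list alone 4 were higher and 1 lower, and the SFRP1 call was lost without day 4. EMT and mesenchyme genes had a median of 0.38 (camera adjusted p = 0.0124; adjusted p = 0.524 with an estimated correlation), with 0 of 10 members passing over all genes in limma, 4 at an unadjusted p under 0.05 and 2 adjusted over the list alone. Fibronectin, FN1, was at 1.26 ± 0.88 (adjusted p = 0.1). The NODAL pathway had a median of 0.61 (camera adjusted p = 0.0487; adjusted p = 0.523 with an estimated correlation). CER1 and NODAL passed over all genes, and adjusted over the list alone 5 were higher and 2 lower. HOX genes (median 0.14, camera adjusted p = 0.0487; adjusted p = 0.624 with an estimated correlation) and cell cycle genes (median 0.08, camera adjusted p = 0.0362; adjusted p = 0.733 with an estimated correlation) had 0 passing members either way in limma, with 3 and 4 at an unadjusted p under 0.05. Of the HOX genes 4 of the 19 measured were above background.

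The remaining 16 lists did not pass with camera. Neuroectoderm genes had a median of 0.095 (adjusted p = 0.61), with the forebrain gene OTX1 higher by 1.34 ± 0.59 and SIX3, HESX1 and POU3F1 (-0.72, named after its value was seen) lower. Adjusted over the list alone 7 members were higher and 5 lower, and camera and fry gave opposite directions. The SOX family had a median of 0.07 (adjusted p = 0.61), and SOX21, a neural SOX factor, fell by 0.93 (adjusted p = 0.0337). Cardiomyocyte structural genes had a median of -0.02 (adjusted p = 0.483), with 0 of 18 members passing in limma, 1 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone; the natriuretic peptide gene NPPB differed by -0.89 ± 1.41 and cardiac troponin I, TNNI3, by -0.65 ± 0.28. In the endothelial and blood list (adjusted p = 0.622) ERG rose by 0.86, in the endoderm list (adjusted p = 0.622) CXCR4 rose by 0.93, and in the epithelial junction list (adjusted p = 0.1) GRHL2 rose by 0.66. In the NOTCH list (adjusted p = 0.0935) the target HEY2 rose by 1.76 ± 0.36, and in the FGF-ERK list (adjusted p = 0.6) FOSL1 fell by 0.75. The metallothionein MT1F fell by 0.56 in the NRF2 and metallothionein list (adjusted p = 0.335), whose median of 0.01 and mean of -0.11 had opposite signs. Adjusted over the list alone, members higher and lower numbered 1 and 2 in the SOX family, 2 and 1 in endoderm, 3 and 1 in NOTCH, 0 and 1 in FGF-ERK and 0 and 4 in the NRF2 list, and 1 was higher in each of the endothelial and junction lists. Without day 4 the calls of OTX1, SIX3, HESX1, SOX21, ERG, CXCR4, GRHL2, FOSL1 and MT1F were lost, and that of HEY2 held. Without day 5 those of SOX21, CXCR4, FOSL1 and MT1F were also lost.

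In limma 0 members passed over all genes in the paraxial mesoderm (camera adjusted p = 0.217), epidermis (0.545), fibroblast matrix (0.483), BMP (0.103), hypoxia (0.483), interferon (0.356) and reference gene (0.483) lists. At an unadjusted p under 0.05 stood 3, 1, 4, 7, 7, 2 and 0 of their members. Adjusted over the list alone, 4 BMP, 3 hypoxia and 1 epidermis members were higher, and 2 hypoxia, 1 fibroblast matrix and 1 interferon members were lower. With camera, 14 of the 30 lists passed, 11 higher and 3 lower. Lists share members, so these are not separate results. The mesendoderm list shares NODAL and CER1 with the NODAL pathway, SP5 and LEF1 with WNT targets, and WNT3 with WNT ligands. Neural crest shares SNAI2 and TWIST1 with EMT and mesenchyme. The pluripotency call was lost without day 3 and without day 4 (camera adjusted p = 0.09 and 0.112) and the NODAL pathway call without day 3 (0.0525). Without day 5 the calls of EMT and mesenchyme (0.137), WNT ligands and antagonists (0.0509), HOX (0.509) and cell cycle (0.792) were lost. Among genes above background the calls of HOX (0.414), NODAL pathway (0.442), WNT ligands and antagonists (0.0577), cell cycle (0.0577) and pluripotency (0.0628) were lost, and after renewed quantile normalisation those of HOX (0.0609) and NODAL pathway (0.0525). With an estimated correlation 0 passed in camera and 1 had an unadjusted p under 0.05, and with fry 0 passed and 7 had an unadjusted p under 0.05. Fry's mixed test, which asks only whether members change in either direction, passed for 12 lists.

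**Figure D2:**
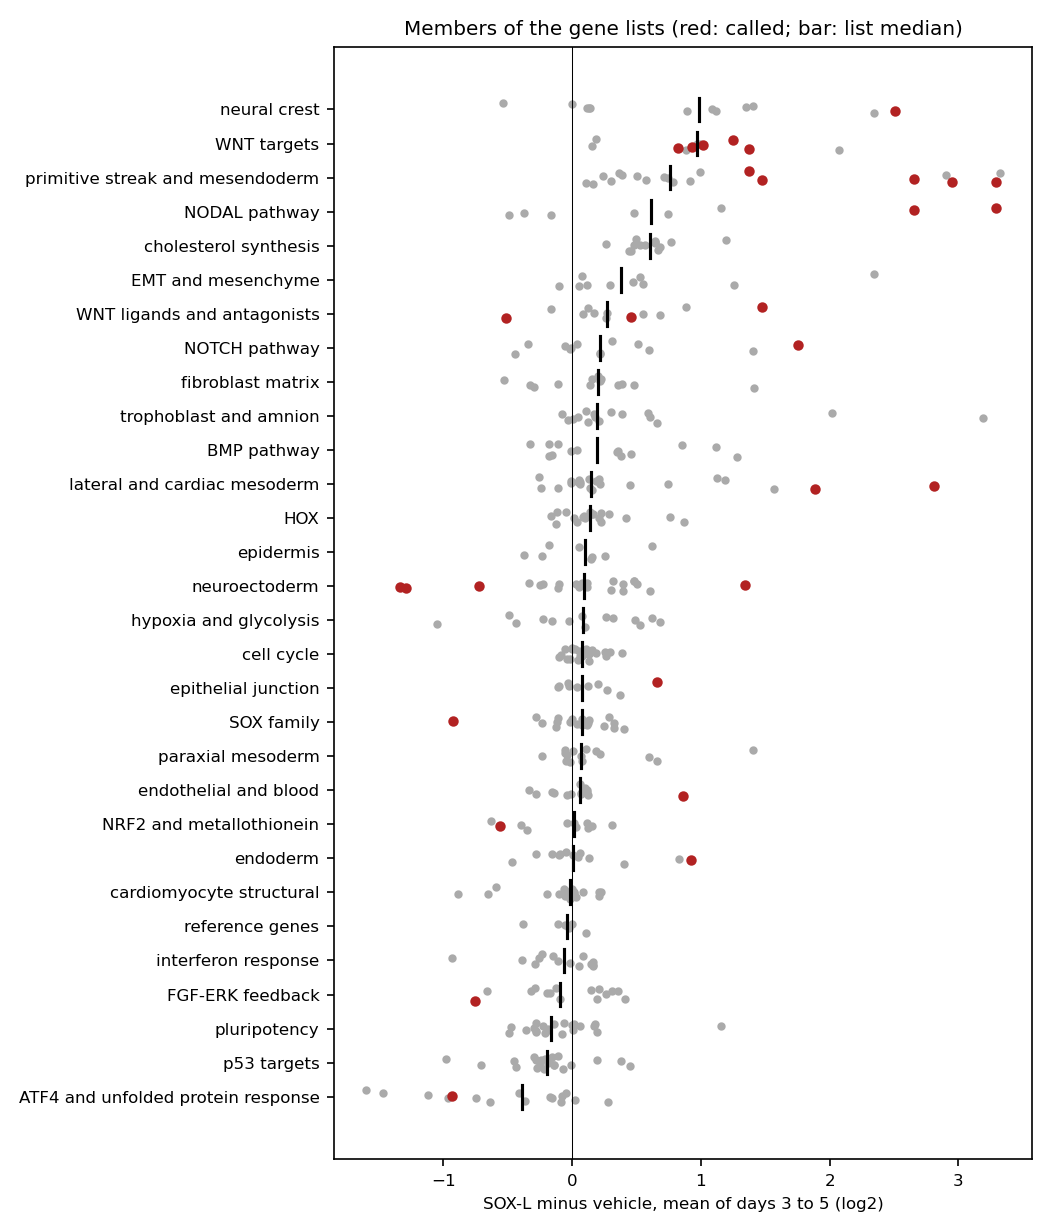
Mean log2 difference between SOX-L and vehicle cells over days 3 to 5 (x axis) for the measured members of the 30 gene lists (y axis); each point is 1 gene, red points passed the adjusted p of 0.05 and black bars are list medians. Mesendoderm and WNT target members all lie to the right of 0, and 14 of the 16 members of the ATF4 list lie to the left.

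Read day by day, differences became more numerous with time. On day 3, 106 genes were at least 2-fold higher and 40 lower with SOX-L, on day 4 the counts were 174 and 102, and on day 5 they were 247 and 136. With no array counted below the background level they were 81 and 22, 142 and 84, and 199 and 110. On day 3 the widest differences were HAND1 (2.94), NODAL (2.92), EPAS1 (2.84), the prostaglandin-degrading enzyme HPGD (2.83) and DACT1 (2.50), and on the other side the small Cajal body RNA SCARNA3 (-1.96), the small nucleolar RNA SNORA2A (-1.90), GRPR (-1.92), the channel TRPC4 (-1.76) and HES3 (-1.60). With vehicle signal raised to the background level, the day 3 values of NODAL, EPAS1 and DACT1 were 2.77, 2.63 and 1.71, so the order of these 3 and HPGD is not set, nor the place of DACT1. On day 4 they were MIXL1 (4.75), neurotensin, NTS (4.43), EPAS1 (4.20), CER1 (3.80) and GABRP (3.75), of which MIXL1, NTS and CER1 were 4.72, 3.35 and 3.44 with vehicle raised to the background level, so the ranks of NTS and CER1 are not set. The lower side held TXNIP (-2.91), an inhibitor of glucose uptake, GRPR (-2.50), TRIB3 (-2.15), CLGN (-2.06) and ULBP1 (-1.99, with SOX-L signal below background).

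On day 5 the apelin receptor APLNR differed by 5.64, NTS by 5.08, SNAI2 by 5.06, GABRP by 4.64 and LRRN4 by 4.31. Vehicle signal of APLNR and NTS was below background that day, so that they are bounded at 4.50 and 4.03 or more and their rank is not set. The lowest values of that day were NIBAN1 (-2.73), skeletal actin ACTA1 (-2.69), tachykinin TAC1 (-2.63), TRIB3 (-2.57) and NPPB (-2.50). SOX-L signal of TAC1 was below background, which leaves a bound of -1.78 and no set rank. These single-day values compare 2 arrays and have no replicate check. At 2-fold or more the same way on all 3 days stood 41 genes, 34 higher and 7 lower. With no array counted below the background level, 33 genes remained, 28 higher and 5 lower. With the sign of any 1 day turned, the count was 0 either way. Across genes the SOX-L differences of days 4 and 5 correlated at r = 0.558, of days 3 and 4 at 0.365 and of days 3 and 5 at 0.207, with no arrays in common. Among olfactory receptor genes alone, a check added after the data were seen, these values were 0.223, 0.041 and 0.007.

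The design also allowed the question of whether SOX-L moved genes the way time in the medium did. The day 3 difference correlated at r = 0.192 with the change of vehicle cells from day 4 to day 5. The day 4 difference correlated at -0.049 with the vehicle change from day 3 to day 5, and the day 5 difference at -0.235 with that from day 3 to day 4; no array entered both sides.

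A change per day shared by both treatments was tested next. The fit took the vehicle and SOX-L arrays of a day as independent, so its p-values may be too small. SOX2 fell by 0.40 per day (SE 0.03, adjusted p = 0.00131) and POU5F1 by 0.40 per day (SE 0.05, adjusted p = 0.00448), while BMP4 rose by 0.54 per day (SE 0.04, adjusted p = 0.00105). The steepest fitted gains were ANKRD1, a cardiac and skeletal muscle ankyrin-repeat protein (1.64 per day, adjusted p = 0.00186), TXNIP (1.58), the retinoic acid receptor RARB (1.54), IGFBP5 (1.42), the kinase ALPK2 (1.39, adjusted p = 0.000276) and EPAS1 (1.39). The steepest fitted losses were the metallothioneins MT1H (-1.71) and MT1G (-1.25), the tryptophan-degrading enzyme IDO1 (-1.13), RN5S67 (-1.12), MIR124-1HG and JAKMIP2-AS1 (-1.11 each). HAND1 and ISL1 rose by 0.88 and 1.09 per day (adjusted p = 0.00368 and 0.00521). Arrays below background were 4 of 6 for MT1H, 3 for RN5S67, 2 for ALPK2 and 1 each for MIR124-1HG and EPAS1. Raised to that level, they gave slopes of -0.86, -0.49, 1.15, -0.97 and 1.34 per day, so the sizes and ranks of these 5 genes are not set.

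For the day trend, both treatments, 1795 genes passed with limma, 823 up and 972 down, with the arrays of a day taken as independent. The split was 927 up and 749 down after renewed quantile normalisation and 951 up and 810 down after centring each array. The count was 38 without day 3, 381 without day 4 and 1 without day 5, and 1065 without the intensity trend. Of the 30 lists 17 passed with camera, 13 up and 4 down, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. With fry 1 passed, pluripotency (adjusted p = 0.0497), and 11 had an unadjusted p under 0.05, and the mixed test passed for 21. The pluripotency list fell, with 10 of 22 members down over all genes and 15 adjusted over the list alone (camera adjusted p = 1.87e-08; adjusted p = 0.313 with an estimated correlation), and the cell cycle list fell with 11 and 14 of 24 (camera adjusted p = 5.14e-06; adjusted p = 0.366 with an estimated correlation). The lateral and cardiac mesoderm list rose with 5 of 22 members up by either adjustment (camera adjusted p = 0.000264; adjusted p = 0.313 with an estimated correlation). In the cardiomyocyte structural list 5 of 18 members rose and 1 fell over all genes, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.366 with an estimated correlation). From day 3 to day 5 the median of the pluripotency list changed by -0.68 in vehicle and -0.60 in SOX-L cells, of the lateral and cardiac mesoderm list by 0.06 and 0.35, and of the cardiomyocyte structural list by 0.31 and 0.08. Among matched random lists, the vehicle value of the mesoderm list stood at the 88.0 percentile and the SOX-L value of the cardiomyocyte list at the 89.3 percentile.

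A treatment-by-day term asked whether the SOX-L difference itself changed from day 3 to day 5. The APLNR difference rose by 2.70 per day (SE 0.14, adjusted p = 0.00203), from 0.24 on day 3 to 5.64 on day 5. Differences of VTCN1, IGFBP7, SULF1, which edits heparan sulfate, SLIT2, a guidance cue, and CCBE1 rose by 1.63, 1.59, 1.39, 1.37 and 1.36 per day (each with adjusted p = 0.0448). Vehicle signal of APLNR, VTCN1 and SULF1 was below background on all 3 days, and slopes with arrays raised to that level were 2.25, 1.58 and 1.13 per day. The difference of EGR1, an immediate early gene of growth factor signalling, fell by 1.08 per day, from 0.53 on day 3 to -1.63 on day 5, and that of UNC5B fell by 0.81, from -0.04 to -1.65, at the same adjusted p. In all 12 genes passed with limma, 10 upward and 2 downward, and 2595 had an unadjusted p under 0.05. The count for treatment by day was 1 without the intensity trend and 102 among genes above background. The cholesterol list had median differences of 0.05, 0.82 and 0.87 on the 3 days and the ATF4 list of -0.05, -0.53 and -0.76. Among matched random lists the cholesterol medians stood at the 78.2, 100 and 100 percentiles.

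**Figure D3:**
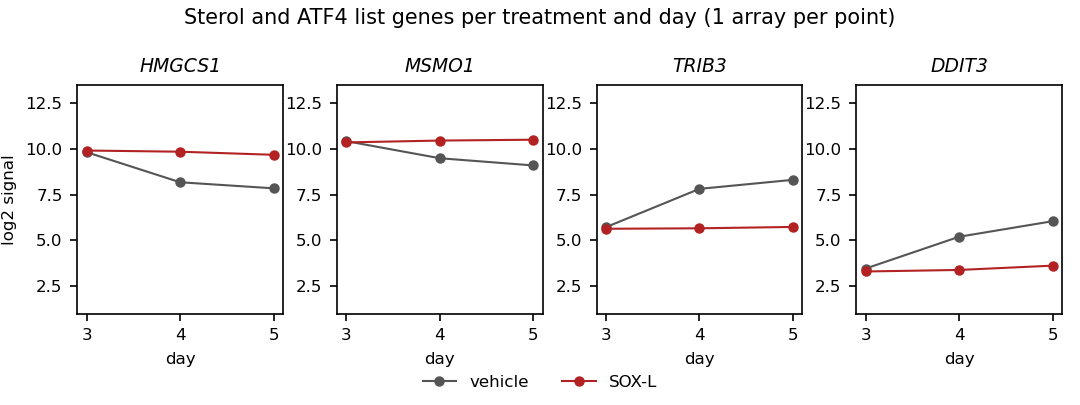
Log2 signal (y axis) of the sterol genes HMGCS1 and MSMO1 and of the ATF4 targets TRIB3 and DDIT3 on days 3, 4 and 5 (x axis) in vehicle (grey) and SOX-L (red) cells, 1 array per point. HMGCS1 differs by 0.09 on day 3 and 1.83 on day 5, and TRIB3 by -0.09 and -2.57.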

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

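Chosen only after the result was seen were the test of the lists for a change of the SOX-L difference with day, the count of gene calls over other splits of the arrays and the tests of the sterol pattern. The list split count was set before its result was known.

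The results here stand out because the difference between SOX-L and vehicle itself changed from day 3 to day 5, by a test of the treatment-by-day term in limma. The difference of APLNR, the apelin receptor, rose by 2.70 per day (SE 0.14, adjusted p = 0.00203), LHFPL6 by 1.14 (SE 0.08, adjusted p = 0.0144) and the lipase LIPG by 0.98 (adjusted p = 0.049). At an adjusted p of 0.0448 stood VTCN1 (1.63 per day), IGFBP7 (1.59), SULF1 (1.39), SLIT2 (1.37), CCBE1 (1.36), the NOTCH target HEY1 (1.29) and SCD, a fatty acid desaturase (0.49), and with a negative slope UNC5B (-0.81) and EGR1 (-1.08), whose differences were -1.65 and -1.63 on day 5. Vehicle signal of APLNR, VTCN1, SULF1 and HEY1 was below the background level on all 3 days. LHFPL6, LIPG and SCD were named after their values were seen. With 3 days and 1 array per treatment and day, each slope rests on 6 arrays, and 1 gene, APLNR, had an adjusted p under 0.05 without the intensity trend.

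For the lists, values are medians over members of each gene's change of the SOX-L difference per day, with the camera adjusted p in brackets. They are not the change of the list's median difference. Positive medians were 0.43 for cholesterol synthesis (4.09e-11), 0.55 for neural crest (1.14e-05), 0.25 for the mesendoderm list (0.00413) and 0.25 for fibroblast matrix (4.94e-05). Hypoxia and glycolysis stood at 0.18 (0.0258), HOX at 0.14 (0.0227) and EMT and mesenchyme at 0.13 (0.00064). WNT ligands stood at 0.12 (0.0151), cell cycle at 0.12 (2.43e-06) and paraxial mesoderm at 0.06 (0.0441). Negative medians were -0.23 for ATF4 targets (1.54e-07), -0.23 for FGF-ERK feedback (0.00336), -0.22 for BMP (4.56e-05) and -0.16 for cardiomyocyte structural genes (0.031). With an estimated correlation 0 of the 30 lists passed in camera (3 at an unadjusted p under 0.05; smallest adjusted p = 0.414), with fry 0 passed (9 at an unadjusted p under 0.05), and the adjusted p for cholesterol synthesis was 0.415.

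From day 3 to day 5 the cholesterol list fell by 0.95 in vehicle and by 0.18 in SOX-L cells (list medians), and the ATF4 list rose by 0.90 in vehicle and by 0.05 in SOX-L cells. Against 1 array out of line, the smaller of the day 4 and day 5 medians was 0.82 (SE 0.09 over members), on arrays not shared between the days. Members move together (estimated correlation 0.918) and a single day has no replicate, so this SE is no error of the day's difference. The median of 0.82 stood at the 100.0 percentile of random lists matched on mean expression, so the list moved apart from genes of like signal. This is no test of an array-wide scaling, which the quantile normalisation before deposit would have removed. A difference in cell number or use of the medium between the cultures may account for the pattern. The ATF4 list rose by 0.903 in vehicle cells against 0.053 with SOX-L, which such a difference would allow. An action of SOX-L on sterol or stress genes would look the same. These arrays cannot tell the 2 apart, and other causes were not tested.

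The number of called genes and lists was recounted over the 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05. The real split called 203 genes and the highest other 0, so 1 of 10 splits called as many. In every other split an effect of SOX-L would enter the error of the fit. That lowers the count, so the 0 is no measure of chance. For lists, the real split called 14 and the highest other 15, so 3 of 10 splits called as many. The splits with 15 put both day 3 arrays with 1 day 5 array, and with the day term in the fit their contrast is the SOX-L difference of day 5 alone. All splits with both arrays of a day on 1 side contrast a single day. Each such contrast, that with 15 too, was counted more than once. Among the 4 splits with 1 array of each day on either side, a count added after the result was seen, 1 called as many genes (203 against 0 at most in the others) and 1 as many lists (14 against 12 at most).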

How the results depend on the processing

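Among the alternatives, the olfactory receptor check of day agreement, the list test for treatment by day and the fit of unnamed probe sets were chosen only after the result was seen. No paired analysis was possible by replicate number because every array carries number 1; the day term pairs the arrays by day in the main test. No named gene's called difference changed sign under the alternatives run. The balance of the day trend, both treatments, turned from 823 up and 972 down to 927 and 749 after quantile normalisation and 951 and 810 after centring, and the neuroectoderm list, which passed in neither, was up in camera and down in fry. For SOX-L vs vehicle, mean of days 3 to 5, the 203 calls became 352 among genes above background, 392 in the upper 50% by mean, 54 without the intensity trend, 1 without the day term, 566 with day as a number and 671 at an adjusted p of 0.1. Leaving out 1 day gave 16 (without day 4) to 1025 (without day 3) calls, sharing 16 and 203 genes with the 203; without day 5 it gave 103, sharing 75. Robust moderation (243), renewed quantile normalisation (192), centring (246) and the mean of probe sets (198) stayed within 1.5 times. Of the 38 named genes with a call, 17 lost it without the trend, 28 without day 4, 8 without day 5, 5 with robust moderation, 1 with the mean of probe sets (WNT3), 1 with day as a number (FOSL1) and 38 without the day term.

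For the day trend, both treatments, 1795 became 1065 without the intensity trend and 3105 at an adjusted p of 0.1, and leaving out 1 day gave 1 (without day 5) to 381 (without day 4). For treatment by day, 12 became 102 above background, 96 in the upper 50%, 1 without the trend, 20 after quantile normalisation, 19 after centring and 170 at an adjusted p of 0.1; with 2 days left no residual degrees of freedom remain, so leaving out a day gave no test. At 1.5-fold, SOX-L vs vehicle on day 3 gave 958 genes, SOX-L vs vehicle on day 4 gave 1261, SOX-L vs vehicle on day 5 gave 1534, and same-direction 2-fold genes on all 3 days became 152. Agreement between days: 3 and 4 was 0.255 by Spearman's rho and 0.509 above background, 3 and 5 was 0.136 and 0.286, and 4 and 5 was 0.405 and 0.675. In olfactory receptor genes the pairs 3 and 4, 3 and 5, and 4 and 5 gave 0.041, 0.007 and 0.223. For the gene lists, SOX-L vs vehicle, 14 calls became 0 with an estimated correlation (1 with an unadjusted p under 0.05), 0 with fry (7), 9 above background, 12 after renewed quantile normalisation, and 12 to 15 when 1 day was left out. For gene lists, day trend, 17 became 0 with an estimated correlation (4) and 1 with fry (11). Of the 29746 other probe sets, limma called 0, and 2079 had an unadjusted p under 0.05 against 1487 by chance. Each count with a day left out rests on 4 arrays, yet for SOX-L vs vehicle it was higher without day 3 and lower without day 4 or 5, so the number of arrays alone does not account for it; the cause was not tested. Signal near background limits HOX, interferon and epidermis members most.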

Other observations

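Of the tests here, the one against T cell RNA was set before its result was known; the comparison of J2 with V segments and the reading of a local transcript were chosen only after the result was seen, as were the genes named.

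Of the 34 genes at least 2-fold higher on all 3 days, some outside the named set were developmental regulators. They were picked after their values were seen and were not tested as a group. The homeobox gene MEIS2, a partner of HOX proteins, went from a mean log2 level of 5.00 in vehicle to 6.84 in SOX-L cells (limma adjusted p = 0.01). SP8, a zinc finger factor of limb and forebrain, went from 4.14, below the background level, to 6.08 (adjusted p = 0.00745), LMX1B from 5.20 to 6.62 (adjusted p = 0.0162) and EYA1, a placode and organ regulator, from 7.59 to 9.05 (adjusted p = 0.00597). The growth factor FGF19 rose by 1.25 ± 0.23 (SD, n = 3 days; adjusted p = 0.0154), the tight junction gene CLDN10 by 1.38 ± 0.15 (adjusted p = 0.00162) and the basement membrane gene FREM1 by 1.61 ± 0.18 (adjusted p = 0.00391).

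Probe sets of the T cell receptor beta locus were higher in SOX-L cells, although these are stem cells. TRBC2, the constant segment, went from 7.48 to 9.03, with daily differences of 1.64, 1.92 and 1.09 (limma adjusted p = 0.0132), and the joining segments TRBJ2-6 and TRBJ2-4 rose by 1.04 and 0.94 (adjusted p = 0.0218 and 0.0289), TRBJ2-4 with both means below the background level. With arrays raised to that level the TRBJ2-4 difference was 0.15, so its size is not set. Against T cell RNA in the samples, the median difference of 15 measured T cell markers, 7 of them above background here, was -0.003 (SE 0.035), with 0 called in limma and 1 at an unadjusted p under 0.05; CD3E stood at 3.45 in vehicle and 3.41 in SOX-L cells and PTPRC at 2.16 in both. Against a misreading by 1 probe set, the 5 uncalled J2 segments lay 0.464 above the V segments in the median (two-sided exact permutation p = 0.00331). That p treats probe sets read on the same arrays as independent, so it measures their spread and not that between arrays. The V segments had a median of 0.008 (SE 0.033), with 0 of 34 called in limma and 4 at an unadjusted p under 0.05, so a local transcript over the J2 and C2 segments is a candidate explanation, a hypothesis found and tested on the same arrays; the labels do not give the cell of origin of the line or its rearrangement at this locus.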
